A study of Mus musculus with 8 samples.

How the data were processed

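Gene expression was measured on 8 mouse gene arrays, each hybridised with amplified complementary DNA from cells sorted out of dissociated skin. The sorted cells carried green fluorescent protein, switched on by Cre recombinase under a tyrosinase promoter, and lacked p75 at the surface, per the labels' protocols. The labels call these cells melanoblasts, the precursors of pigment cells, in pups of 4 days, and melanocyte stem cells in mice of 21 days. P4_WT and P21_WT hold 2 arrays each, and P21_KO holds 4 arrays from mice in which Cre could recombine floxed alleles of B-raf and C-raf. The labels describe the arrays as biological replicates, and for the wild-type groups as separate animals. P21_KO replicates 2, 3 and 4 share a number in their labels, whose meaning is not stated, so it is not known whether these 3 of the 4 arrays come from independent animals. The p-values measure the spread between these samples, and are too small in both comparisons if they do not, since the spread is shared.

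The deposited values are on a log2 scale and were made with RMA in Affymetrix Expression Console, per the submitters' processing notes. Versions are not given in the sources used here. The values ran from 0.913 to 12.2. RMA subtracts background, brings all arrays to one distribution and summarises the probes of each probe set. It compresses differences near the floor, so fold changes of genes that read below the arrays' median in a group are likely to be understated, whether or not the text repeats this. The amplification used before labelling, which small cell numbers require, adds spread that cannot be separated from that between animals.

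The value table had 41345 rows. The platform annotation listed 25335 of them with a gene. Exactly 1 gene symbol was given for 23521, several for 1814, and 16010 were unnamed here. The gene ID of 23328 single-symbol rows was found in the mouse gene table, built on assembly GRCm38.p6 and used only for names and chromosomes, and 0 symbols needed an update. Of the 1082 genes with several single-symbol probe sets, the probe set with the highest mean over all arrays was kept, which left 22180 genes. No filter on dim genes was applied in the main analysis.

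A linear model with the 3 groups was fitted to all 8 arrays with limma 3.58.1 (lmFit and eBayes, R 4.3.3), so that both comparisons shared one estimate of the spread with 5 residual degrees of freedom. The age comparison is P21_WT minus P4_WT and the genotype comparison is P21_KO minus P21_WT. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over all genes, and a gene was called at an adjusted p under 0.05. The number of arrays limits the precision, above all for the groups of 2. On simulated values for the 22180 genes with 200 changed, the age fit recovered 28% of changes of 1 log2 unit and 94% of changes of 2 log2 units. The genotype fit recovered 46% and 94%. The fits also called 9 and 5 unchanged genes.

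Gene lists were tested with camera in limma at its preset correlation of 0.01, over the 26 of 27 lists with at least 5 measured members. Of 474 list entries, 430 were measured. The red blood cell list had too few measured members and was not tested. Camera compares a list with all other genes and fry asks whether its members move one way on balance. For the relation between the comparisons, which share the P21_WT arrays with opposite sign, the correlation and covariance of log2 changes across genes were set beside values from 100 simulations with no effect. The simulations draw from each gene's residual spread, a choice made after a first run with the moderated spread had been seen. It gives a larger difference from the observed covariance than the first run did.

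The genes named were chosen by a rule fixed before the data were examined, as were the lists, the tests and the alternatives in the closing section, except where stated. The rule takes the 8 largest rises and 8 largest falls among called genes whose groups do not overlap. Where none is called, it takes the 5 per direction with the smallest p. It adds up to 4 members with the smallest p from each called list and up to 2 from other lists, and always takes Braf, Araf, Mitf, Sox10, Kit, Dct, Tyr, Ednrb and Mki67 where measured. Unnamed gene models, olfactory and vomeronasal receptors, small RNAs and immune receptor segments were skipped. From lists that were not called, the text names the first member only, a narrowing made after the values were seen.

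Alternatives covered the arrays in the fit, the prior, array weights, 3 further normalizations, a filter on dim genes, the choice of probe sets, blocks for replicate and label numbers, chromosome 6, thresholds, other list tests and leaving out each array. The annotation does not mark control rows. For the alternative that tests every probe set, the 5333 rows with IDs below the first annotated one were taken as controls, which is an assumption from the numbering.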

Results

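The series sets melanoblasts from the skin of young pups against melanocyte stem cells from older mice, and wild-type melanocyte stem cells against those lacking B-raf and C-raf, to find genes involved in keeping these stem cells. Arrays of one group correlated at 0.954 to 0.974 across the 22180 genes. P21_WT arrays correlated with P21_KO arrays at 0.950 to 0.977, which spans the range within groups. Wild-type arrays of different age correlated at 0.942 to 0.946. P4_WT replicate 2 differed from the other arrays in sex-linked genes. Its Xist value, an RNA of the inactive X chromosome, was 8.94 against 1.95 to 2.77 elsewhere, and its value for the Y-linked Eif2s3y was 1.94 against 6.92 to 7.87.

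Braf, a target of the knockout, had a mean log2 value of 6.26 ± 0.41 (SD, n = 4) in P21_KO and 6.59 ± 0.85 (SD, n = 2) in P21_WT. The change of -0.34 ± 0.36 (SE) did not pass limma's test (adjusted p = 0.944). Single P21_WT arrays read 5.99 and 7.20, and P21_KO arrays read 5.66 to 6.57. The change was -0.94 without P21_WT replicate 1 and 0.27 without replicate 2. The probe set summarises probes along the transcript, whose place relative to the floxed part is not known here, so this value checks the deletion little. Araf, which encodes a related kinase, was 0.40 ± 0.21 (SE) higher in P21_KO (limma adjusted p = 0.832).

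The age comparison asks how melanocyte stem cells differ from melanoblasts. In P21_WT, genes of cell division and pigment production were lower as lists than in P4_WT. Cell cycle inhibitors (median 0.13), Schwann cell and glial genes (median 0.40) and immediate early genes (median 1.47) were higher as lists. With an estimated correlation only the cell cycle call held, and limma's adjusted p was 0.157 for pigmentation, 0.515 for the inhibitors, 0.29 for glial genes and 0.104 for immediate early genes. The largest measured falls were in Slc24a4, an ion exchanger gene (30.9-fold, log2 -4.95 ± 0.31 SE), Gap43, a growth cone protein gene (27.0-fold, log2 -4.75 ± 0.35 SE), and Oca2, a melanosome protein gene (25.9-fold, log2 -4.70 ± 0.30 SE). The largest measured rises were in Defb6, a defensin gene (27.0-fold, log2 4.75 ± 0.66 SE), and Krt77, a keratin gene (15.0-fold, log2 3.90 ± 0.57 SE). Slc24a4 (3.11) and Gap43 (3.13) in P21_WT, and Defb6 (2.11) in P4_WT, read below the median of all values on those arrays. Compression near the floor may understate these folds and picking the largest changes may overstate them, so they do not rank the genes. In all, limma called 357 of 22180 genes, 168 higher and 189 lower in P21_WT.

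Other large rises were those of Clca3a2 (12.8-fold), the potassium channel gene Kcnk1 (12.6-fold), the amino acid transporter gene Slc36a2 (9.23-fold), Dusp15 (8.33-fold), Anxa8 (7.96-fold) and Drp2 (7.64-fold). Other large falls were those of the hair keratin genes Krt27 (24.5-fold), Krt71 (16.3-fold) and Krt25 (15.7-fold), the amino acid transporter gene Slc7a8 (16.8-fold) and the ribonucleotide reductase gene Rrm2 (12.7-fold). The hair keratins varied widely within P4_WT, with an SD of 1.89 for Krt27, and read below the arrays' median in P21_WT. Their folds are therefore not well measured. Over the alternative fits the log2 change ranged from -5.95 to -3.28 for Krt27, -5.42 to -2.63 for Krt71 and -4.90 to -3.04 for Krt25.

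All 37 measured cell cycle genes were lower in P21_WT, and 19 fell past the threshold over all genes (31 adjusted over the list alone). The list's median was -1.51, and its camera call held with an estimated correlation (limma adjusted p = 0.0207). Birc5 fell by 3.36 ± 0.18 (SE), Cdk1 by 2.75 ± 0.18, Ccnb2 by 3.42 ± 0.30 and Aurkb by 2.72 ± 0.26 on the log2 scale. Birc5 (2.70) and Aurkb (2.94) read below the arrays' median in P21_WT, so the sizes of their changes are not well measured. Mki67, a marker of cycling cells, had a mean of 7.68 ± 0.25 (SD, n = 2) in P4_WT and 4.79 ± 0.04 (SD, n = 2) in P21_WT. The list of inhibitors and quiescence genes was higher (limma camera adjusted p = 0.0102), with an adjusted p of 0.515 with an estimated correlation. Its median was only 0.13, and 6 of its 18 members were lower. Past the threshold, 2 members rose (4 adjusted over the list alone). These were Cdkn1a (1.60 ± 0.16 SE) and Cdkn1b (1.13 ± 0.18 SE), which encode inhibitors of cyclin-dependent kinases. Btg2 (1.16) and Klf4 (1.04) did not pass. Without P21_WT replicate 2 the list's adjusted p was 0.162.

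All 20 measured pigmentation genes were lower in P21_WT, 5 of them past the threshold (11 adjusted over the list alone), with a median of -1.28 (limma camera adjusted p = 1.55e-12). With an estimated correlation the adjusted p was 0.157. Besides Oca2, Gpr143 fell by 2.71, Trpm1 by 2.79 and Rab38 by 1.91. Tyr, the gene of the rate-limiting enzyme of melanin synthesis, was lower by 1.94 with an adjusted p of 0.0636 in limma, and Dct, a melanoblast marker, differed by -0.30 ± 0.42 (SE). The list of lineage regulators was not called (limma camera adjusted p = 0.354). In it, Lef1, a transcription factor gene of Wnt signalling, fell by 2.44 ± 0.26 (SE), the 1 called member of 17 (2 lower and 1 higher adjusted over the list alone). Mitf changed by -0.30, Kit by -0.76, Ednrb by -1.37 and Sox10 by 0.73, none past the threshold.

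Schwann cell and glial genes were higher in P21_WT as a list (limma camera adjusted p = 0.00333), with an adjusted p of 0.29 with an estimated correlation. The list's median was 0.40 and its mean 0.19, with 4 members lower. Of 14 measured members, 6 rose and 1 fell past the threshold (6 and 2 adjusted over the list alone). Mal (2.06 ± 0.22 SE), Egr2 (1.81 ± 0.19) and Pmp22 (1.09 ± 0.15), genes of myelinating cells, rose, while Gap43 fell. All 16 immediate early and dissociation genes were higher, 9 past the threshold (15 adjusted over the list alone), with a limma camera adjusted p of 1.79e-19 and an adjusted p of 0.104 with an estimated correlation. Fosb rose by 2.71, Nr4a1 by 1.62, Hspa1a by 1.59 and Hspa1b by 1.39.

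Wnt pathway genes were lower (limma camera adjusted p = 0.0111; with an estimated correlation, adjusted p = 0.515), with Lef1, Axin2 (-1.10) and Wif1 (-1.50) past the threshold among 24 members (8 lower and 2 higher adjusted over the list alone). Fzd1 (-0.94) did not pass. Without P4_WT replicate 1 or P21_WT replicate 1 the list was not called, with adjusted p up to 0.128, nor with dim genes left out (0.0655). Genes of oxidative phosphorylation were lower in 20 of 21 cases (limma camera adjusted p = 7.52e-08; with an estimated correlation, adjusted p = 0.29). None passed singly and 7 did adjusted over the list alone, with Cox5a at -1.02, Ndufs1 at -0.74, Ndufb5 at -0.78 and Uqcrfs1 at -0.78. Glycolysis genes were lower in 12 of 14 cases (limma camera adjusted p = 0.00128; with an estimated correlation, adjusted p = 0.104). None passed over all genes, and 7 lower and 1 higher did adjusted over the list alone. Hk2 was at -1.61, Pgk1 at -0.75, Pgam1 at -0.94 and Gapdh at -0.74.

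Markers of other skin cells moved with age too. Hair shaft and inner root sheath genes were lower in P21_WT (limma camera adjusted p = 1.91e-06; with an estimated correlation, adjusted p = 0.43), with 3 of 14 members past the threshold (6 adjusted over the list alone). Tchh, at -4.06, did not pass and read below the arrays' median in P21_WT. Its change is not well measured, since it ranged from -5.87 to -2.25 over the alternative fits. The list's mean was 5.19 in P4_WT replicate 1 and 3.75 in replicate 2, against 2.86 to 2.99 on the P21 arrays. Keratinocyte genes were higher as a list (limma camera adjusted p = 0.00227; with an estimated correlation, adjusted p = 0.562). None of 15 passed over all genes and 1 did adjusted over the list alone, with Krtdap at 1.52, Krt10 at 1.39, Jup at 0.68 and Krt14 at 0.96. Without P4_WT replicate 2 the list's adjusted p was 0.549.

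Endothelial genes (limma camera adjusted p = 0.00556; with an estimated correlation, adjusted p = 0.597) and macrophage, dendritic and T cell genes (limma camera adjusted p = 0.017; with an estimated correlation, adjusted p = 0.674) were lower in P21_WT. In both lists 0 members passed, over all genes or adjusted over the list alone. The endothelial mean was 5.08 in P4_WT replicate 2 and 3.31 in replicate 1, and the immune mean 5.56 and 2.97. Without P4_WT replicate 2 the endothelial list had a median of 0.08 (adjusted p = 0.599) and the immune list was higher, with a median of 0.34 (limma camera adjusted p = 0.02). Without P21_WT replicate 1 the immune list's adjusted p was 0.0996, and with the wild-type arrays alone it was 0.0578. With dim genes left out the adjusted p was 0.0946 for the endothelial and 0.0655 for the immune list. Named members were Tek (-0.88), Cdh5 (-2.04), Emcn (-1.51), Eng (-0.63), Ptprc (-1.28), Fcer1g (-1.93), Coro1a (-0.98) and C1qb (-0.48).

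The other lists were not called by age. Their limma camera adjusted p was 0.0768 for the TGF-beta and BMP pathway (Id2 fell by 1.57), 0.0787 for skeletal muscle (Tnnt3, 0.82), 0.0855 for fibroblasts (Fbln1 fell by 1.73) and 0.139 for mast cells (Cma1, -1.83). It was 0.328 for cytoskeleton and integrins (Itgb4 at 1.11, called here but in none of the 8 fits that left out 1 array), 0.33 for adipocytes (Pparg, -0.65), 0.615 for ERK targets (Egr1, 1.18) and 0.704 for both PI3K-AKT-mTOR components (Rheb, -0.55) and the Notch pathway (Heyl fell by 1.40). It was 0.8 for hair follicle stem cells (Nfatc1, 1.38), 0.835 for pericytes (Rgs5, -1.97) and 0.934 for both RAS-RAF-MEK-ERK components (Map2k1, -0.93) and apoptosis genes (Zmat3, -0.74). The median, mean and test differed in sign for the last 3 of these lists. Some were called by limma's camera in other fits. Without P4_WT replicate 1 the fibroblast list (median -0.61) and the mast cell list (median -1.32) were lower. Without P4_WT replicate 2 the mast cell median was 0.03, and Cma1 read 2.36 and 5.92 on these arrays in order of replicate. The TGF-beta list was lower (median -0.36) and the muscle list higher (median 0.28) without P21_WT replicate 2. The TGF-beta list was also called with every probe set tested (adjusted p = 0.0425), and the fibroblast list without chromosome 6 (adjusted p = 0.0327).

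The number of genes called by age rested on the pooled spread and on single arrays. It was 121 and 119 without P21_WT replicates 1 and 2, 233 without P21_KO replicate 3, and 49 with the wild-type arrays alone. Of the 40 named genes called by age, 17 kept the call without P21_WT replicate 1 and 17 without replicate 2. Only 14 kept it whichever array was left out: Aurkb, Birc5, Ccnb2, Cdk1, Cdkn1a, Drp2, Egr2, Gap43, Gpr143, Kcnk1, Lef1, Mal, Oca2 and Slc24a4. With the wild-type arrays alone 14 of the 40 kept it, which leaves out Ccnb2, Cdkn1a, Egr2, Gpr143 and Mal. Axin2 and Wif1 kept it in 1 of the 8 such fits, and Heyl and Krt71 in 2.

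**Figure D1:**
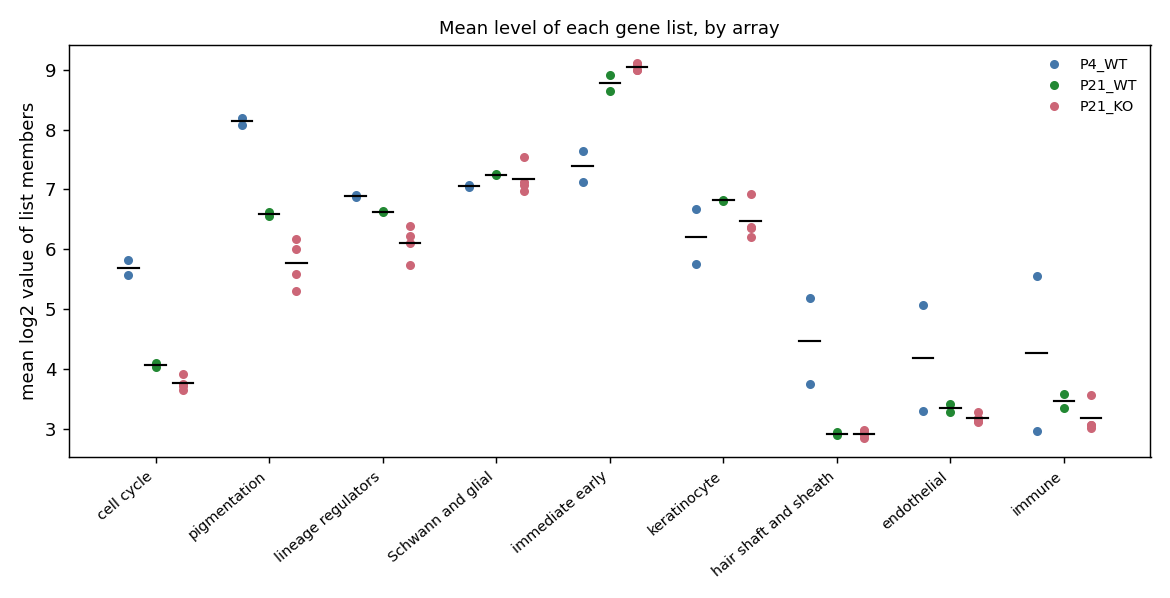
Mean log2 value of the members of 9 gene lists (y axis) on each of the 8 arrays, by group (colours); points are arrays and black bars are group means. The pigmentation mean was 8.14 in P4_WT, 6.60 in P21_WT and 5.77 in P21_KO, and the endothelial and immune means of P4_WT rested on replicate 2.

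The genotype comparison asks which genes of melanocyte stem cells differ with the knockout. Pigmentation genes, melanocyte lineage regulators and targets of ERK, the kinase downstream of Raf, were lower as lists in P21_KO. So were cell cycle, Wnt pathway, oxidative phosphorylation and keratinocyte genes, while immediate early genes were higher. No single gene passed the threshold. With an estimated correlation limma's adjusted p was 0.309 for pigmentation and for lineage regulators and 0.344 for ERK targets. In that test 0 lists were called, as with fry. Tyr was at 7.58 ± 0.43 (SD, n = 2) in P21_WT and 5.67 ± 0.58 (SD, n = 4) in P21_KO. Etv5, an ERK target gene, was at 7.69 ± 0.57 (SD, n = 2) and 5.20 ± 0.51 (SD, n = 4). Limma called 0 of 22180 genes. It also called 0 with array weights, after cyclic loess normalization and at an adjusted p under 0.10. At an unadjusted p under 0.05 there were 1447 genes, 629 higher and 818 lower, where 1109 would come by chance.

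The lower genes with the smallest p, none past the threshold, were Thbs2 (-1.78 ± 0.20 SE), Cpm (-2.52 ± 0.31), Syt4 (-2.85 ± 0.36), Etv5 (-2.50 ± 0.36) and Tinagl1 (-1.67 ± 0.25). The higher ones were Adap1 (1.31 ± 0.19), Cfap20 (1.55 ± 0.23), the histone gene H1f2 (1.59 ± 0.26), the metallothionein gene Mt3 (1.08 ± 0.18) and Plekhf1 (0.99 ± 0.17). Their limma adjusted p lay between 0.229 and 0.284. Without P21_WT replicate 2, 15 genes were called, Thbs2 among them. Without P21_WT replicate 1 there were 2, and without P21_KO replicate 1 there was 1, Syt4 (limma adjusted p = 0.0164).

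All 20 pigmentation genes were lower in P21_KO, with a median of -0.63 (limma camera adjusted p = 9.17e-11). With an estimated correlation the adjusted p was 0.309. The list's mean was 6.18, 6.00, 5.59 and 5.30 on the P21_KO arrays in order of replicate, against 6.56 and 6.63 in P21_WT. The lowest, P21_KO replicate 4, stood apart from all arrays on the second principal component (48.4 against -22.5 to 10.2). No member passed over all genes and 2 did adjusted over the list alone. Tyr was at -1.91 ± 0.35 (SE), Pmel at -2.04 ± 0.54, Mlana at -1.83 ± 0.52 and Dct at -1.12 ± 0.36. Of 17 lineage regulators 15 were lower, with a median of -0.52 (limma camera adjusted p = 1.48e-05; with an estimated correlation, adjusted p = 0.309), and 1 passed adjusted over the list alone. Lef1 was at -0.98, Cited1 at -0.65, Tfap2b at -0.46 and Ednrb at -1.07. Mitf, the master regulator of the lineage, was at -0.78 ± 0.34 (SE), Kit at -0.95 ± 0.64 and Sox10 at 0.07 ± 0.18.

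ERK targets were lower in 14 of 19 cases (limma camera adjusted p = 0.0149; with an estimated correlation, adjusted p = 0.344), and 1 passed adjusted over the list alone. Besides Etv5, Etv1 was at -0.75, Spry4 at -1.19 and Phlda1 at -0.43. The other 5 targets were higher, Egr1 (0.48) among them. Without P21_WT replicate 1 the list's adjusted p was 0.191, and with dim genes left out it was 0.0578. Cell cycle genes were lower in 29 of 37 cases (limma camera adjusted p = 3.27e-06; with an estimated correlation, adjusted p = 0.309), with Cdk1 at -0.73, Cdt1 at -0.63, Tpx2 at -0.60 and Birc5 at -0.49. Cdk1, Tpx2 and Birc5 read below the arrays' median in P21_KO, so the sizes of their changes are not well measured. None passed adjusted over the list alone, and Mki67 was at -0.58 ± 0.32 (SE). Wnt pathway genes were lower in 17 of 24 cases (limma camera adjusted p = 0.00153; with an estimated correlation, adjusted p = 0.371), and 4 passed adjusted over the list alone. Besides Lef1, Fzd1 was at -0.67, Ctnnb1 at -0.72 and Lrp5 at -0.76. Without P21_WT replicate 2 the list's adjusted p was 0.103.

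Immediate early and dissociation genes were higher in 14 of 16 cases (limma camera adjusted p = 0.00242; with an estimated correlation, adjusted p = 0.555), and none passed adjusted over the list alone. Nr4a1 was at 0.46, Dnajb1 at 0.58, Atf3 at 0.45 and Egr1 at 0.48. Without P21_WT replicate 2 the list's adjusted p was 0.313. Oxidative phosphorylation genes were lower in 18 of 21 cases (limma camera adjusted p = 0.0153; with an estimated correlation, adjusted p = 0.787), and 1 passed adjusted over the list alone. Ndufa4 was at -0.84, Cox5b at -0.44, Ndufa1 at -0.47 and Ndufb5 at -0.30. The call was lost without P21_WT replicate 2 or P21_KO replicate 2 (adjusted p up to 0.42) with dim genes left out (0.0578) and without chromosome 6 (0.0544), which carries Braf and Ndufa4. Keratinocyte genes were lower in 13 of 15 cases (limma camera adjusted p = 0.0271; with an estimated correlation, adjusted p = 0.839), and none passed adjusted over the list alone. Krt17 was at -1.47, Dsp at -0.82, Krt14 at -0.51 and Dsg3 at -0.63. Only 3 of the 8 fits that left out 1 array called that list, with adjusted p up to 0.223. Those without P4_WT replicate 1 or 2 are among these 3, and amount to the same fit for this comparison. The call was lost after cyclic loess (0.0652) and with dim genes left out (0.0578).

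The remaining lists were not called by genotype. Their limma camera adjusted p was 0.07 for adipocytes (Car3, 3.17 ± 1.10 SE, from below the arrays' median in P21_WT and with 2.42 to 7.40 in P21_KO), 0.153 for the Notch pathway (Hes1, -0.49), 0.266 for both cytoskeleton and integrins (Itga1, -0.92) and fibroblasts (Lox, 1.60), and 0.283 for endothelium (Eng, -1.29). It was 0.287 for pericytes (Pdgfrb, -0.30), 0.446 for macrophage, dendritic and T cells (Lyz2, -0.96), 0.549 for both glycolysis (Hk1, -0.54) and cell cycle inhibitors (Cdkn2d, 1.08), and 0.707 for skeletal muscle (Myh1, -0.38), the TGF-beta and BMP pathway (Smad3, -0.87) and apoptosis genes (Bcl2l1, 0.82). It was 0.777 for Schwann cells and glia (Fabp7, -1.72), 0.783 for mast cells (Gata2, 0.18), 0.793 for PI3K-AKT-mTOR components (Rheb, 0.44), and 0.963 for RAS-RAF-MEK-ERK components, hair follicle stem cells (Krt19, 0.24) and hair shaft genes (Msx2, 0.43). The median, mean and test differed in sign for the Schwann, mast cell, RAS-RAF-MEK-ERK and hair follicle stem cell lists. Some lists were called by limma's camera in other fits. The macrophage, dendritic and T cell list was lower in P21_KO with the P21 arrays alone (adjusted p = 0.0421). For this comparison, leaving out P4_WT replicate 1 or 2 amounts to that same fit. Without P21_KO replicate 1 the adipocyte list was higher (0.032) and the cytoskeleton (0.032) and fibroblast (0.0172) lists were lower. The muscle list was lower without P21_WT replicate 2 (0.00891), and without chromosome 6 the adipocyte list was higher (0.0266).

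**Figure D2:**
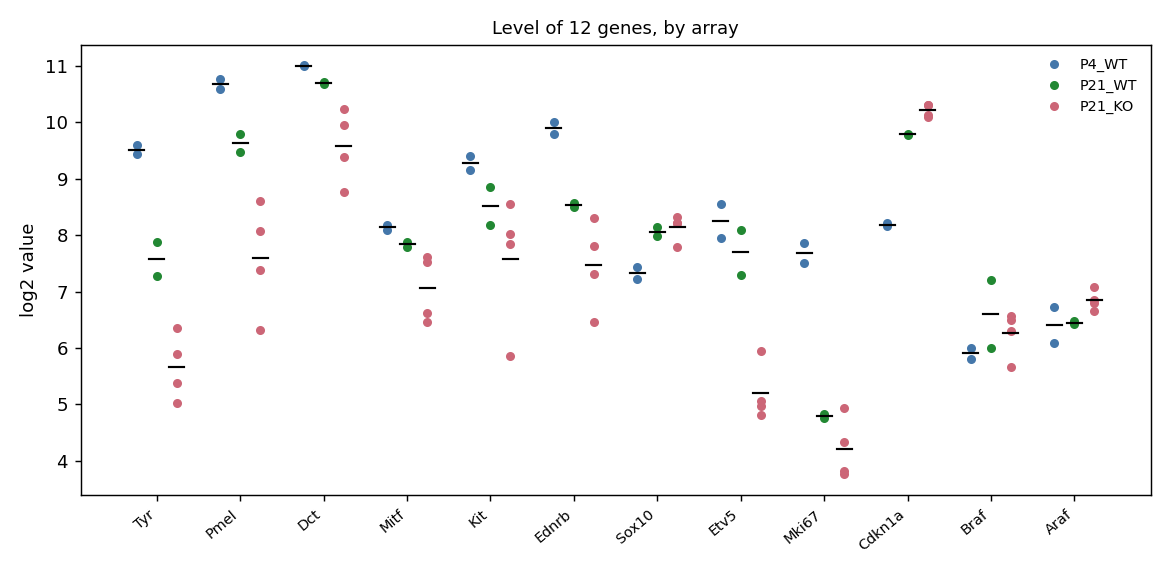
Log2 value of 12 named genes (y axis) on each of the 8 arrays, by group (colours); points are arrays and black bars are group means. Tyr and Etv5 were lower on all 4 P21_KO arrays than on both P21_WT arrays, and Braf overlapped between these groups.

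The genotype changes were set beside the age changes to see whether genes that differ between ages also differ with the knockout. Across genes, which are not independent replicates, the correlation of the log2 changes was 0.0014. Simulations with neither an age nor a genotype effect gave a mean of -0.577. Real age changes, absent from those simulations, would shrink such a correlation, so the covariances are the fairer comparison. The covariance was 0.000227 against a simulated -0.0558, a difference of 0.0561, or 0.0860 with dim genes left out. With each P21_WT array used for a single comparison, a check added after the data were seen, the correlations were 0.214 and 0.247. Of the 357 genes called by age, 260 (72.8%) had a genotype change in the same direction, against a mean of 33.6% in 50 simulations with no genotype effect. The simulations draw from each gene's own spread, so they do not cover genes that shift together on an array. Among the 15 splits of the P21 arrays described below, the highest other covariance difference was 0.0457, against the real 0.0561. Neither the share nor the covariance therefore settles whether the relation exceeds such shared shifts.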

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

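The tests of explanations in this part were chosen as such only after the results they bear on had been seen, though the fits that leave out 1 array or chromosome 6 had been planned. Each P21_KO level named next was picked because 1 of the 4 arrays lay far from the rest, its gap to the nearest array, as a ratio to the range, passing the critical value of Dixon's test. Of 181 lists and genes tested 11 did so, and chance flags about 1 in 20 groups.

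P21_KO replicate 1 was highest for the fibroblast list mean (6.30 against 5.76 to 5.80, ratio 0.913), lowest for the mast cell list mean (2.23 against 2.40 to 2.41, ratio 0.979) and highest for Tfap2b (ratio 0.839). P21_KO replicate 4 was highest for the macrophage, dendritic and T cell list mean (3.57 against 3.02 to 3.08, ratio 0.903). It was lowest for Rrm2 (ratio 0.918), Notch2 (ratio 0.871) and Apaf1 (ratio 0.838). P21_KO replicate 3 was highest for Hey2 (ratio 0.914) and C1qb (ratio 0.831) and lowest for Cdt1 (ratio 0.868). P21_KO replicate 2 was highest for Cidec (ratio 0.838).

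Pigmentation genes were lower in P21_KO as a list, a call lost with an estimated correlation (limma adjusted p = 0.309). A single array is argued against, since the highest camera adjusted p without any 1 P21 array was 2.77e-05 at the preset correlation. Strain alleles on chromosome 6, where Braf lies, stay open: the adjusted p without that chromosome was 4.92e-10, but only 1 member lies there, so leaving it out decides nothing, and alleles of Mitf, also there, may act on the others. A lower share of melanocyte cells stays open. Of the 7 members well above background, 3 departed from the members' mean, Tyrp1 by 0.70, Tyr by -0.51 and Pmel by -0.64. All 3 still fell, and unequal falls may come from unequal probe response. An effect of the knockout in the cells themselves stays open as well, as untested.

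Schwann cell and glial genes were higher in P21_WT as a list, a call lost with an estimated correlation (limma adjusted p = 0.29). A higher share of the same Schwann cells stays open. Of the 6 members well above background, 2 departed from the members' mean and changed in opposite directions, Mal (2.06) and Fabp7 (-1.22). The test took opposite changes as evidence against that explanation. The change of Fabp7 was not past the threshold singly, so its fall is not sure and the test decides little. A single array is argued against, with a highest adjusted p of 0.00956 without any 1 wild-type array. Other glial cells taking the place of earlier ones, and a change with age in the sorted cells, stay open and untested. The gate removed cells with surface p75, which immature Schwann cells carry.

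Endothelial and immune genes were lower in P21_WT as lists, calls lost with an estimated correlation (limma adjusted p = 0.597 and 0.674). Cells of other types in P4_WT replicate 2 are a candidate explanation, since without that array the endothelial adjusted p was 0.599 and the immune list was higher, with an adjusted p of 0.02. Cdh5 had a mean of 6.29 ± 2.26 (SD, n = 2) in P4_WT and 4.24 ± 0.16 (SD, n = 2) in P21_WT. A difference between the animals themselves, which do differ in sex-linked genes, stays open and untested.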

How the results depend on the processing

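In settings chosen before the data were seen and 1 added afterwards, which used each P21_WT array for a single comparison (age and genotype relation 0.0497), most results kept direction and side of the threshold: 1697 values of genes by age and 1605 by genotype, and 494 and 479 of lists. Of the others, 152 gene values by age lost their call with the direction kept and 34 gained one, against 0 and 2 by genotype, while 20 list values by age and 24 by genotype lost it in this way and 7 and 8 gained one. Much of this agreement was fixed beforehand. All 1605 gene values by genotype are of uncalled genes that stayed uncalled. Fits without a P4_WT array cannot move genotype changes, nor can fits without a P21_KO array move age changes. The age comparison gave 49 genes with only the 2 groups compared, 674 at an adjusted p under 0.10, and 1092 at an unadjusted p under 0.05 with a 2-fold change, where genotype gave 225. Lists called by age numbered 5 with fry and 1 with an estimated correlation, and by genotype 0 and 0, or 5 with dim genes left out. The relation was 0.0860 with dim genes left out. Arrays with the same replicate number did not deviate together (correlations of -0.0372 to 0.00573), so the numbers pair nothing, and a replicate block gave 45 genes by age and 0 by genotype, with 13 and 7 lists. It ended the call of ERK targets by genotype (limma camera adjusted p = 0.116) and called the TGF-beta list by age (0.0288). Under that block, the direction of uncalled camera tests by genotype turned for the following lists, given with their medians: RAS-RAF-MEK-ERK (0.0229), PI3K (0.0674), TGF-beta (0.15), apoptosis (0.0101), hair follicle stem cells (-0.12) and mast cells (-0.0285). The direction of other uncalled camera tests also turned, though often not the sign of the median, given here. With 2 groups these were hair shaft (-0.0362) and hair follicle stem cells (0.0655) by genotype. With array weights it was hair follicle stem cells by genotype (-0.00548), and with cyclic loess PI3K (-0.0363) and apoptosis (-0.0283) by age and RAS-RAF-MEK-ERK by genotype (0.0327). With quantile normalization they were PI3K (-0.0432) and apoptosis (-0.0350) by age, and with median centring apoptosis (-0.0311) and, among genes, the change of Araf (-0.0323) by age. With dim genes left out they were apoptosis (-0.0760) and hair follicle stem cells (-0.26) by age, and TGF-beta (-0.0300) and hair shaft (0.00544) by genotype. With every probe set it was RAS-RAF-MEK-ERK by age (0.0687), with the mean of probe sets the same list (0.0620) and hair follicle stem cells by genotype (-0.0462), and without chromosome 6 RAS-RAF-MEK-ERK by age (0.0342) and genotype (0.0225).

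Leaving out each array in turn, a lone array being assumed to vary like the other groups, gave 119 to 338 genes by age and 0 to 15 by genotype, 10 to 13 and 5 to 10 lists, and an age and genotype relation of 0.0485 to 0.0829. Of 40 named genes called by age, 14 were called in all these fits, 13 under the replicate block and 8 in every setting. Where the direction of camera's test by age turned in a fit, list medians ranged over -0.23 to -0.0287 (ERK targets), -0.0392 to 0.15 (RAS-RAF-MEK-ERK), -0.11 to 0.0241 (Notch), -0.26 to 0.0719 (apoptosis), -0.46 to -0.0805 (hair follicle stem cells), -1.53 to 0.0816 (endothelium), -2.00 to 0.34 (immune cells), -1.32 to 0.0319 (mast cells), -0.40 to 0.28 (pericytes) and 0.0240 to 0.28 (muscle). By genotype, such medians ranged over -0.0585 to 0.0686 (RAS-RAF-MEK-ERK), -0.16 to 0.0353 (PI3K), -0.11 to 0.0943 (TGF-beta), -0.0983 to 0.0870 (hair shaft), -0.0502 to 0.0768 (hair follicle stem cells), -0.0154 to 0.17 (Schwann cells) and -0.24 to 0.15 (muscle). Among gene changes, those of Coro1a (-2.00 to 0.0429), Tpsb2 (-3.35 to 0.0319) and Araf (-0.29 to 0.36) turned by age. By genotype Egr1 (-0.00422 to 0.97), Acta1 (-2.83 to 0.00776), Braf (-0.94 to 0.27) and Sox10 (-0.00453 to 0.19) did.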

Other observations

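The tests in this part were chosen before their results were seen, though after the comparisons they bear on.

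A hypothesis was that the knockout cells lie further along the direction of the age change than wild-type cells. The excess covariance of 0.0561 was the highest of all 15 splits of the 6 P21 arrays into 2 and 4, with 1 split as large, the real one, and 0.0457 as the highest other. With 15 splits a share under 0.05 cannot be reached, so the question stays open.

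A further hypothesis was that strain alleles on chromosome 6, carried along with floxed Braf, add to the genotype differences. Of 1201 genes there, 79 (6.58%) had an unadjusted p under 0.05 by genotype, against 6.54% of 20793 genes elsewhere. The odds ratio was 1.01 (Fisher's exact p = 0.952, two-sided, genes not being independent), which gives no sign of an excess on that chromosome.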
